A study of Zea mays with 16 samples.

How the data were processed

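Leaf 4 of 20-day-old maize plants was scratch-inoculated on its major veins with GFP-labelled Pantoea stewartii, the bacterium that causes Stewart's wilt, or with inoculation buffer as a wounding control. Pieces 1 cm long, beginning 0.3 cm from the scratch and without the midrib, were taken 1 day later. Each library came from the pooled tissue of about 15 plants, per the labels' protocols. The 2 genotypes were the inbred B73, as the wild type, and a line homozygous for a Mutator transposon allele of pan1, called R2 in the labels and here. The design holds 2 genotypes, 2 treatments and 4 replicates, 16 libraries in all. The series design calls the replicates biological.

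RNA was turned into 3′ tag libraries, in which a transcript gives reads near its 3′ end, and sequenced as 100 bp single-end reads at a mean of about 8000000 reads per sample, per the labels' protocols. The authors deposited raw counts of reads per gene, whole numbers with no normalisation. The submitters' processing notes name STAR 2.6.0c and the B73 RefGen_v4 build without giving their role. The counting program, the annotation release, the read filters and the treatment of reads that match several genes are not given in the sources used here. Values of near-identical gene copies and of overlapping genes are therefore uncertain. The second deposited table holds a normalised signal. A comparison of both tables showed each of its values to be the deposited count multiplied by 1 factor per library, so the authors' scaling is a single effective library size per library. These factors differed from the trimmed mean of M values (TMM) factors computed here by at most 0.98%. All columns of both tables belonged to labelled samples, and no row lacked a gene identifier.

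Library totals ran from 3872655 to 7259058 counts. A count of 0 in a library allows up to 3 counts, which corresponds to between 0.393 and 0.787 CPM, the depth-scaled unit that edgeR computes from counts and effective library sizes. Folds against a group with no count were computed against 3 counts over the whole group and are lower bounds. PCR copies were not told apart from separate molecules, so these floors and the intervals cover counting error only. The 24 pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom from 6.11 to 30.2, so all 16 were kept as separate replicates.

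Of 46335 features, 27105 had a count and 17279 passed the expression filter of edgeR. These held 99.69% of all counts. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, 1 mean per group over all 16 libraries, no further term, and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. The comparisons were infection against mock in each genotype and averaged over both, R2 against B73 in each treatment, and the interaction. Values per gene are CPM with TMM factors, as mean ± SD over 4 libraries. Standard errors of log2 fold changes (SE) were derived from the F statistic. Alternatives were size factors of DESeq2 1.42.0, no expression filter, the Wald test of DESeq2, limma 3.58.1 with a trend on log2 of the deposited values plus 1, a fit of only the groups compared, each library left out in turn, and the replicate number as a block. Combinations of the block with these settings, and the block with each number left out, were added after the data were seen. Overlaps were tested with Fisher's exact test, two-sided. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.

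Whether the replicate numbers pair the libraries was decided before the calls of both fits were compared. The labels give the same numbers to all groups and no date or batch for them. Deviations from the group means correlated in all 24 same-numbered pairs of libraries, with coefficients across genes from 0.11 to 0.51 and a median of 0.34. Libraries of another number and another group gave coefficients from -0.53 to 0.18 with a median of -0.075, and 14 of the 16 libraries correlated best with their own number. By the criterion that every such pair exceed 0.1, the numbers pair the libraries. The pairing thus rests on the data, and blocked values stand beside each result that they change.

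Both scripts for tests across genes were checked on simulated data. Counts were simulated from the mean per replicate number, the library sizes and the dispersions of the real genes, so that they held the differences between the numbers. In the 17088 genes tested there, the fit without the block recovered 54.0% of the 2-fold and 85.5% of the 4-fold changes for infection in B73, and 50.0% and 85.0% for infection in R2. With the block these shares were 74.5% and 94.5% in B73 and 69.0% and 96.0% in R2. For the interaction they were 16.0% and 65.0% without the block and 47.0% and 81.0% with it. For infection averaged over genotypes, the changed genes included those changed only in infected B73, which were counted at their fold in B73. The averaged change of these genes was smaller, so the shares for the average are not directly comparable with those within a genotype. These shares were 53.0% and 82.5% without the block and 70.0% and 89.0% with it. For genotype in mock they were 47.0% and 87.0% without it and 73.0% and 96.0% with it, and for genotype in infected 55.0% and 86.5% without it and 73.5% and 92.0% with it. At most 1 unchanged gene was called per comparison without the block. With it, the unchanged genes were 27 of 365 called for infection in B73, 10 of 175 for infection in R2, 15 of 333 for the average and 6 of 134 for the interaction. They were 16 of 185 called for genotype in mock and 19 of 350 for genotype in infected. In this simulation the share of unchanged genes among blocked calls thus exceeded the threshold of 0.05 for infection in B73 and in R2 and for both genotype comparisons.

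Gene names could be given for few features. The reference gene table used here, of assembly Zm-B73-REFERENCE-NAM-5.0, matched 153 of the 46335 identifiers, all of them microRNA genes, and none of these was tested. The identifiers of the tested genes are not paired with names in the files, so at most 2 identifiers per direction and comparison are given and no function is attached to them. For this reason 32 lists of defence, hormone, photosynthesis and cell-type genes, fixed before the data were examined, could not be tested, since 0 of them had a matched member. The transcript level of pan1 as a check of the labels is likewise not reported here. Coordinates are not given, because the build of the table differs from the build named for the counts.

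The rule for genes named in the text was fixed before the data were examined: the largest fold changes among called genes with a mean of at least 1 CPM in the higher group and no overlap between the groups. It gave genes for the genotype comparisons only. For infection, genes were chosen after their values were seen. They are the largest fold changes among called genes with the same direction in every same-numbered pair, from the blocked fit within each genotype and from the fit without the block for the average.

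The rows of the deposited tables follow the chromosomes, since 152 of the 153 matched microRNA genes stood in the order of the reference table. Called genes were counted in 346 windows of 50 tested genes along these rows, and the highest window share was compared with 100000 random placements. In 20 simulated random placements this test made 1 call, and it found 7 of 10 planted windows. Neighbouring windows above the limit that holds 95% of the random highest shares, with a gap of at most 1 window, were joined into segments. The place of pan1 was interpolated between its flanking microRNA genes by counting the coding genes of the reference table. Between the neighbouring microRNA genes on either side, this interpolation missed 51 microRNA genes of known row by a median of 7 and at most 70 rows. The interval around pan1 spans 2008 rows, and over 164 intervals of 1 to 1.5 times that length the interpolation missed 125 microRNA genes by a median of 32 and at most 177 rows. These longer intervals were chosen after the data were seen.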

Results

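Transcript levels were measured in 16 libraries of maize leaf 4, from the vein tissue next to a scratch that carried either Pantoea stewartii or buffer. The 4 groups were mock-inoculated B73, infected B73, mock-inoculated R2 and infected R2, with 4 libraries each. R2 carries a transposon insertion in pan1, which encodes a receptor-like protein known from the polarised divisions that form the stomatal subsidiary cells. Libraries of mock-inoculated B73 held 5309490 to 7259058 counts and those of infected B73 4316684 to 5811462. Libraries of mock-inoculated R2 held 4625073 to 5734655 counts and those of infected R2 3872655 to 5455850.

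The largest component of the variation between libraries followed the replicate number. The first principal component of log2 CPM took 23.6% of the variance, and the replicate number accounted for 69.7% of its scores. Genotype accounted for 68.6% of the second component, which took 18.1% of the variance. Treatment accounted for 48% of the third, which took 12.1%. The replicate number has more levels than genotype or treatment and so accounts for more by chance, which makes these shares not directly comparable. The biological coefficient of variation was 0.209 without the replicate number in the model and 0.126 with it.

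**Figure D1:**
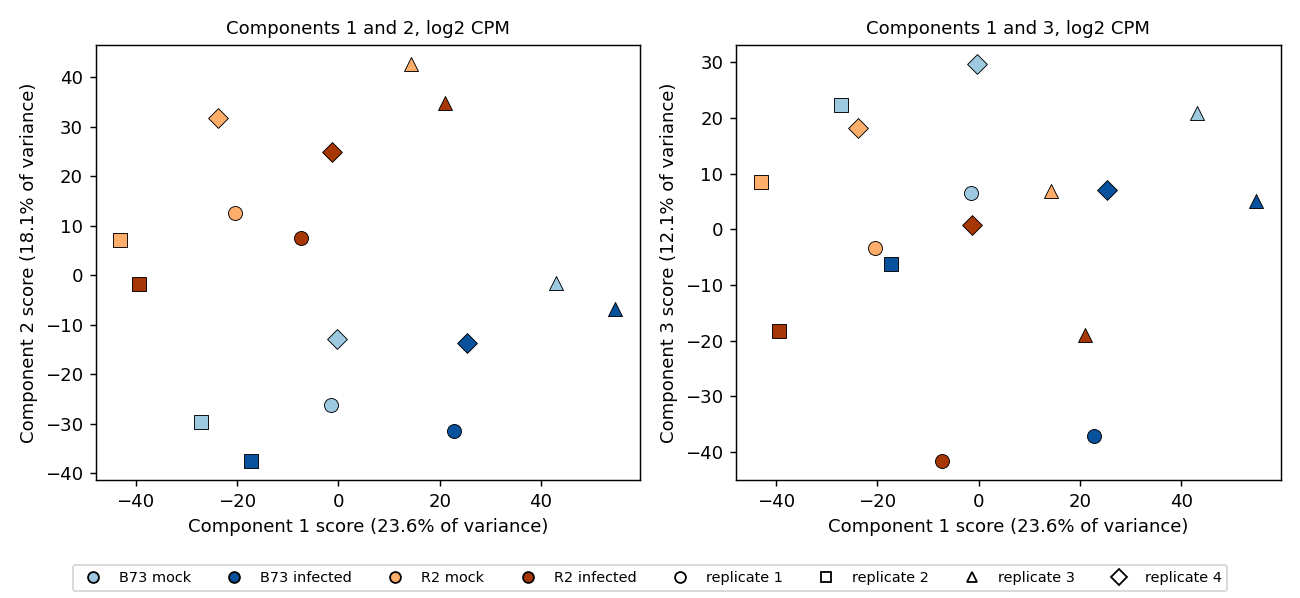
Scores of the 16 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM; colours give the group and symbols the replicate number. Component 1 (23.6% of variance) sets replicate 3 to the right of the other numbers within each group, component 2 parts the genotypes within each replicate number, and component 3 parts infected from mock libraries within each number and genotype.

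Infection changed transcript levels when both genotypes were considered together, and most genes that changed rose. Averaged over genotypes, 52 genes were called, of which 48 were higher and 4 lower in infected leaves. The Wald test of DESeq2 called 277, 217 higher and 60 lower, and without an expression filter edgeR called 82, 80 higher and 2 lower. The median log2 fold change was 0.93 among the higher genes, and 20 of them were at least 2-fold higher. Zm00001d045092 rose in B73 from 1.63 ± 1.15 to 6.44 ± 1.85 CPM and in R2 from 0.318 ± 0.378 to 4.33 ± 2.54 CPM (SD, n = 4), a log2 fold change of 2.79 (SE 0.42, edgeR adjusted p 0.0108). Zm00001d051080 rose from 0.463 ± 0.0994 to 2.42 ± 0.949 CPM in B73 and from 0.188 ± 0.271 to 2.02 ± 0.948 CPM in R2, also by 2.79 (SE 0.43, edgeR adjusted p 0.0108), and by 3.43 without mock R2 replicate 2 (edgeR adjusted p 0.0102). With limma these log2 fold changes were 1.75 and 1.25. The 4 mock R2 libraries together held only 7 counts of Zm00001d045092 and 4 of Zm00001d051080. Zm00001d000001 fell from 12.2 ± 3.58 to 4.10 ± 1.71 CPM in B73 and from 5.44 ± 1.14 to 2.67 ± 1.36 CPM in R2, a log2 fold change of -1.29 (SE 0.25, edgeR adjusted p 0.0306). Zm00001d040807 fell from 39.2 ± 6.97 to 28.7 ± 3.22 CPM in B73 and from 51.6 ± 10.9 to 32.5 ± 3.66 CPM in R2, a log2 fold change of -0.56 (SE 0.11, edgeR adjusted p 0.0456). Among the called genes with at least 1 CPM, 47 higher and all 4 lower genes moved in the same direction in all 8 same-numbered pairs. With the replicate number as a block, 1255 genes were called, 781 higher and 474 lower, and these included all 52. Among those 1255, 163 were at least 2-fold higher and 15 at least 2-fold lower.

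The count of 52 rested on single libraries. It was 16 without infected B73 replicate 1, 17 without mock B73 replicate 2 or replicate 4, 18 without mock R2 replicate 1 or replicate 4, 26 without infected R2 replicate 1, 28 without mock R2 replicate 3 and 31 without infected R2 replicate 3. It was 97 without infected B73 replicate 2 and 87 without infected R2 replicate 4. Zm00001d000001 lost its call without any 1 of 8 libraries, namely any mock R2 library, mock B73 replicates 2 and 4, infected B73 replicate 1 and infected R2 replicate 3. Zm00001d040807 lost it without any 1 of 13 libraries, all except mock B73 replicate 3, mock R2 replicate 3 and infected B73 replicate 2. Over all alternatives the adjusted p ran from 5.95e-10 to 0.0878 for Zm00001d000001 and from 7.37e-08 to 0.118 for Zm00001d040807. Both of the named higher genes stayed called without any 1 of the 16 libraries. The blocked count of 1255 was 476 without replicate 1 and 816 without replicate 4.

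**Figure D2:**
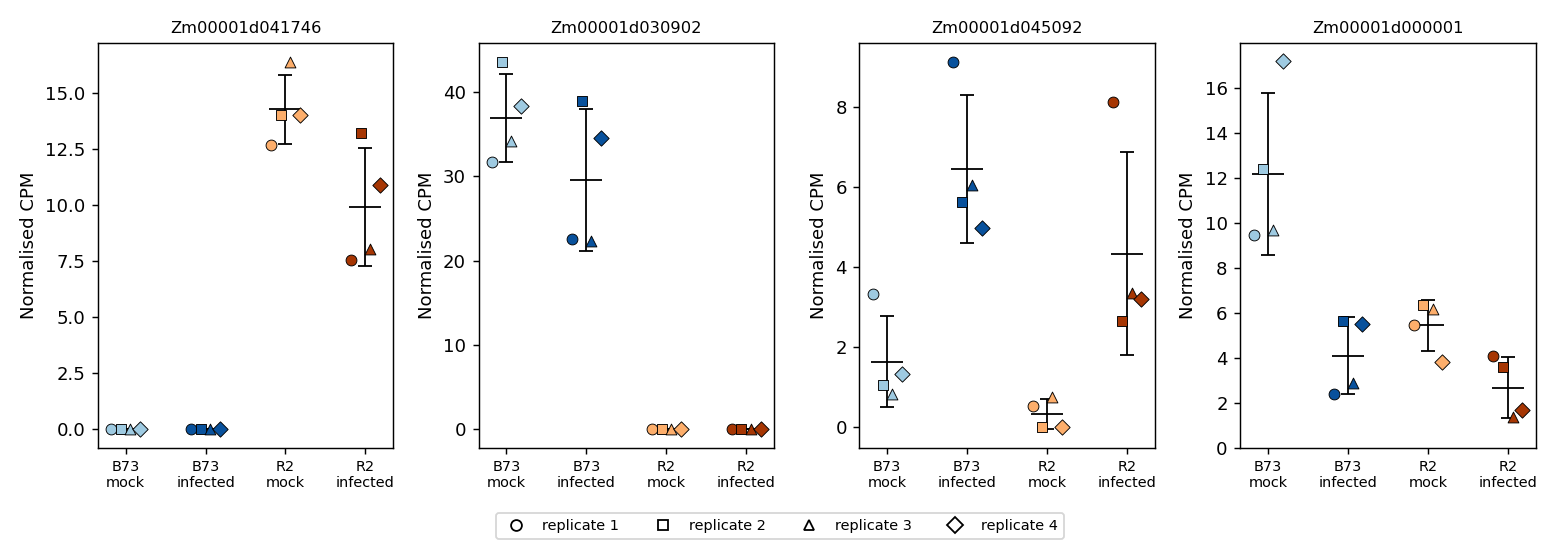
Normalised CPM (y axis, linear) of 4 named genes in each library; colours give the group, symbols the replicate number, horizontal bars the mean and error bars the SD of 4 libraries. Zm00001d041746 has no count in the 8 B73 libraries and Zm00001d030902 none in the 8 R2 libraries, while Zm00001d045092 is higher and Zm00001d000001 lower in infected than in mock leaves in all 8 same-numbered pairs.

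In B73, the response to infection became detectable at the level of single genes when same-numbered libraries were compared. With the replicate block 379 genes were called, 282 higher and 97 lower, and 92 of the higher and 12 of the lower genes differed at least 2-fold. Zm00001d033957 went from 3.56 ± 1.26 to 20.9 ± 14.7 CPM (SD, n = 4), a blocked log2 fold change of 2.46 (SE 0.53, edgeR adjusted p 0.013). Its groups overlapped, with 4.27 CPM in infected replicate 2 and 4.94 CPM in mock replicate 3. Zm00001d051080 rose by 2.31 on the log2 scale (edgeR adjusted p 0.0229), from only 11 counts in the mock B73 libraries together. Zm00001d039426 went from 3.52 ± 1.96 to 0.768 ± 0.388 CPM, a blocked log2 fold change of -2.15 (SE 0.44, edgeR adjusted p 0.00884). Zm00001d021459 had a blocked log2 fold change of -1.80 (SE 0.26, edgeR adjusted p 0.00072) with 20.8 ± 18.6 CPM in mock and 7.06 ± 9.08 CPM in infected leaves, so that its groups overlapped and only the pairs separated. Without the block its log2 fold change was -1.52, which became -0.76 without mock B73 replicate 2 and -2.93 without infected B73 replicate 2, with none of these called. Without the block edgeR called 0 genes in B73, with a lowest adjusted p of 0.13 and 1191 genes at an unadjusted p under 0.05. The Wald test of DESeq2 called 21 and limma called 0. With limma and the block, the log2 fold change was 1.18 for Zm00001d051080 and -1.28 for Zm00001d039426.

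In simulated data, 27 of the 365 blocked calls for infection in B73 were unchanged genes. The blocked count in B73 was 96 without replicate 1 and 174 without replicate 4. Without replicate 1, the blocked log2 fold change was 2.01 for Zm00001d033957 (edgeR adjusted p 0.103) and -1.96 for Zm00001d039426 (edgeR adjusted p 0.118). Without replicate 4 it was 2.33 for Zm00001d051080 in B73 (edgeR adjusted p 0.0923). Over all alternatives in B73, the adjusted p of each of the 4 genes reached 1, and the lowest was 2.49e-24 for Zm00001d033957, 0.00114 for Zm00001d039426, 8.29e-16 for Zm00001d021459 and 0.01 for Zm00001d051080.

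In R2, infection likewise raised more genes than it lowered once same-numbered libraries were compared. With the replicate block 204 genes were called, 159 higher and 45 lower, and 51 of the higher and 7 of the lower genes differed at least 2-fold. Zm00001d045092 had a blocked log2 fold change of 3.61 (SE 0.52, edgeR adjusted p 0.00144) and Zm00001d051080 one of 3.23 (SE 0.66, edgeR adjusted p 0.0164). The first was 4.48 without replicate 3 (edgeR adjusted p 0.00147) and the second 4.49 without replicate 2 (edgeR adjusted p 0.0211). Without the block they were 4.33 without mock R2 replicate 3 and 4.54 without mock R2 replicate 2, with neither called. With limma and the block they were 1.95 and 1.31. The 4 mock R2 libraries together held 7 counts of the first gene and 4 of the second, so these folds rest on few counts. For the second gene, mock R2 replicate 2 had 0.576 CPM, which corresponds to 3 counts. Zm00001d048192 had a blocked log2 fold change of -2.02 (SE 0.30, edgeR adjusted p 0.00144), with 12.6 ± 21.1 CPM in mock and 3.18 ± 5.58 CPM in infected leaves (SD, n = 4). Most of its counts came from replicate 2, and without the block its log2 fold change was 0.44 when mock R2 replicate 2 was left out. Zm00001d038049 had a blocked log2 fold change of -1.71 (SE 0.34, edgeR adjusted p 0.0123), with 18 ± 19.3 CPM in mock and 4.50 ± 3.9 CPM in infected leaves; it was -0.98 without replicate 2. With limma and the block, the log2 fold change of Zm00001d048192 was -1.27. Without the block edgeR called 0 genes in R2, with a lowest adjusted p of 0.18 and 972 genes at an unadjusted p under 0.05. The Wald test of DESeq2 called 18 and limma called 0, and edgeR called 1 gene without infected R2 replicate 1.

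In simulated data, 10 of the 175 blocked calls for infection in R2 were unchanged genes. The blocked count in R2 was 32 without replicate 1, 128 without replicate 2, 133 without replicate 3 and 129 without replicate 4. Zm00001d048192 had a blocked log2 fold change of -2.43 without replicate 2 (edgeR adjusted p 0.103). That of Zm00001d038049 was -1.77 without replicate 1 (edgeR adjusted p 0.0616) and -0.98 without replicate 2 (edgeR adjusted p 0.269). That of Zm00001d051080 in R2 was 3.04 without replicate 3 (edgeR adjusted p 0.06) and 3.02 without replicate 4 (edgeR adjusted p 0.0637). Over all alternatives in R2, the adjusted p ran from 4.03e-10 to 0.713 for Zm00001d045092, from 0.0019 to 0.919 for Zm00001d051080, from 2.52e-11 to 1 for Zm00001d048192 and from 1.69e-09 to 1 for Zm00001d038049.

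The infection responses of B73 and R2 overlapped. In the blocked fits, 104 of the 282 higher genes in B73 were also among the 159 higher genes in R2, where independent lists would share 2.59 (Fisher's exact p 7.37e-153). Of the 97 lower genes in B73, 20 were among the 45 lower genes in R2, against 0.253 for independent lists (Fisher's exact p 3.39e-34). No gene was called in opposite directions. In R2, 279 of the 282 genes called higher in B73 had a positive fold change (98.9%), with a median log2 fold change of 0.61 against 0.83 in B73. These genes were selected on their values in B73; the 159 genes called higher in R2 had medians of 0.84 in R2 and 0.76 in B73. Over all 17279 tested genes, the log2 fold changes of both genotypes, which share no library, had a Pearson correlation of 0.48 and a Spearman correlation of 0.40 without the block. These correlations and the Fisher tests are across genes, which are not independent replicates. Although no library is shared, same-numbered libraries varied together, so an infection difference peculiar to a replicate number could enter both responses. Both lists of called genes also came from 1 fit with a shared spread per gene. Without an expression filter the Pearson correlation was 0.10, and with the block and without replicate 1 it was 0.36.

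**Figure D3:**
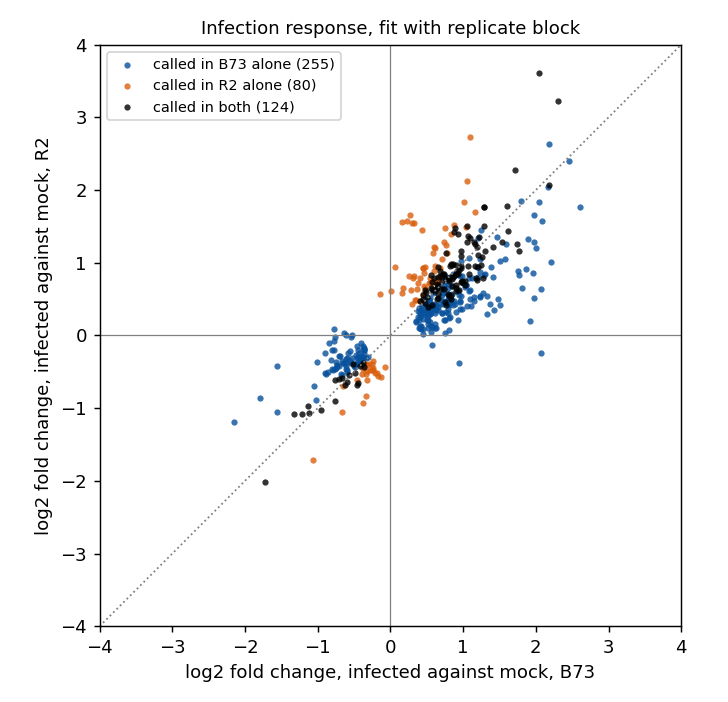
Log2 fold change of infected against mock leaves in B73 (x axis) and R2 (y axis) for the 459 genes called in either genotype by the fit with the replicate block; each point is 1 gene, and the dotted line marks equal change. Of these, 124 were called in both genotypes, 255 in B73 alone and 80 in R2 alone, and 451 had the same sign in both; a gene called in 1 genotype alone is not thereby shown to differ between them.

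The question of whether R2 responds differently from B73 was tested by the interaction. No gene was called by edgeR, either without the block (287 genes at an unadjusted p under 0.05, lowest adjusted p 1) or with it (538 genes at an unadjusted p under 0.05). DESeq2 and limma also called 0 genes. With the block and no expression filter edgeR called 17 genes. A difference between the responses was thus not detectable among the genes that passed the filter. The power was limited, since in simulated data the interaction test recovered 16.0% of 2-fold differences without the block and 47.0% with it.

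R2 and B73 differed in 227 genes in mock-inoculated leaves, and the largest differences were in genes with counts in only 1 of the lines. Of the called genes, 85 were higher and 142 lower in R2, with a median log2 fold change of 1.81 among the higher and -1.41 among the lower genes. These medians were the same with genes that had no count in one group set to their lower bound. At least 4-fold differences were fitted for 39 higher and 45 lower genes. Zm00001d041746 had 14.3 ± 1.57 CPM in R2 (SD, n = 4) and no count in B73, at least 112-fold higher (edgeR adjusted p 1.46e-06). Zm00001d035748 had 12.2 ± 2.48 CPM in R2 and no count in B73, at least 95.9-fold higher (edgeR adjusted p 1.95e-06). Zm00001d030902 had 36.9 ± 5.23 CPM in B73 and no count in R2, at least 255-fold lower in R2 (edgeR adjusted p 6.68e-07). Zm00001d031159 had 10.2 ± 3.27 CPM in B73 and no count in R2, at least 70-fold lower (edgeR adjusted p 1.11e-05). Across both treatments, 18 genes with at least 1 CPM in R2 had no count in any of the 8 B73 libraries, and 11 with at least 1 CPM in B73 had none in the 8 R2 libraries. The fit with the replicate block called 540 genes, 203 higher and 337 lower, and all 227 were among them.

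In infected leaves the genotypes differed in 243 genes, 92 higher and 151 lower in R2. Zm00001d041746 was again without a count in B73, against 9.93 ± 2.65 CPM in R2 (SD, n = 4), at least 68.8-fold higher (edgeR adjusted p 5.43e-06). Zm00001d041814 had 9.16 ± 0.378 CPM in R2 and no count in infected B73, at least 63.5-fold higher (edgeR adjusted p 3.03e-06). Zm00001d030902 had 29.6 ± 8.41 CPM in B73 and no count in R2, at least 189-fold lower in R2 (edgeR adjusted p 9.37e-07). Zm00001d029722 had 13.6 ± 4.54 CPM in B73 and no count in R2, at least 86.7-fold lower (edgeR adjusted p 2.08e-05). Of the higher genes, 68 were shared with the 85 found in mock leaves, against 0.453 for independent lists (Fisher's exact p 5.04e-153). Of the lower genes, 110 were shared with the 142 in mock leaves, against 1.24 (Fisher's exact p 1.63e-219). No gene was called in opposite directions in the 2 treatments, and over the 292 genes called in either treatment, which were selected for their difference, the log2 fold changes had a Pearson correlation across genes of 0.98. Over all tested genes the Pearson correlation was 0.78 and the Spearman correlation 0.42. Here too the genes are not independent replicates, and both lists came from 1 fit with a shared spread per gene. The fit with the replicate block called 595 genes, 213 higher and 382 lower, and all 243 were among them.

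The genes that differed between R2 and B73 in mock leaves lay together in the gene order. The highest share in a window of 50 tested genes was 32.0%, against a mean of 1.31%, and none of 100000 random placements exceeded 18% (permutation p 1e-05, the smallest they can give). Windows above the 95% limit of 10% formed 2 segments. One of 100 tested genes lay between the microRNA genes MIR164e and MIR482 and held 18 called genes, 7 higher and 11 lower in R2. The other, of 500 tested genes, lay between MIR482 and MIR166i and held 94, of which 30 were higher and 64 lower. Together they held 3.47% of the tested genes and 112 of the 227 called genes (49.3%). The segments were defined in mock leaves, and in the infected libraries 20.8% of the tested genes inside them were called, against 0.71% outside (Fisher's exact p 1.3e-118). This is not an independent check, because the same 2 lines were compared in the same fit. Of the calls in infected leaves, 68 of the 92 higher and 110 of the 151 lower genes were also called in mock leaves. The Fisher test also treats neighbouring genes as independent. In infected leaves the highest window share was 36%, and 2 windows outside both segments also passed the limit, with 14.0% and 12%. With the replicate block the highest share in mock leaves was 40%.

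**Figure D4:**
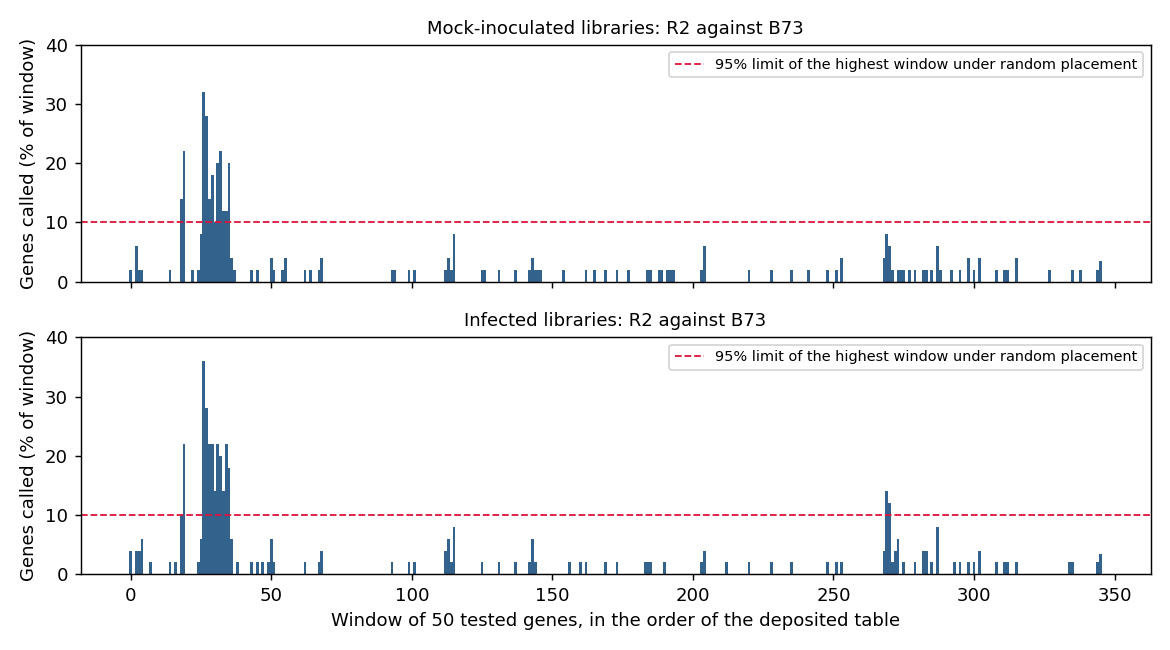
Share of genes called between R2 and B73 in percent (y axis) in consecutive windows of 50 tested genes in the row order of the deposited table (x axis), for mock (top) and infected libraries (bottom); the dashed line is the 95% limit of the highest share under random placement. The tall bars near the left reach 32.0% in mock and 36% in infected libraries, against a limit of 10%.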

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

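The tests of replicate 1, and the choice of the infection genes named here, were made after the results were seen. The splits of the libraries and the shuffled blocks were set before their results were seen.

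In 9 of 76 groups of 4 values, 1 library stood apart from the others of its group. Chance does so in about 1 of 20 independent groups. The groups here were not independent, as most hold genes chosen for their change and several of the 9 hold Zm00001d048192. Groups without a count cannot stand apart, so these shares are not directly comparable. The total of mock B73 replicate 2 was 7259058 counts, against at most 5596378 in its group. Zm00001d048192 was far higher in replicate 2 than in the other numbers of every group, at 145 CPM in mock B73, 49.1 CPM in infected B73, 44.1 CPM in mock R2 and 11.5 CPM in infected R2. Zm00001d021459 reached 63.9 CPM in mock R2 replicate 2. Zm00001d033957 reached 22.0 CPM in infected R2 replicate 4 and 4.22 CPM in mock R2 replicate 2. Zm00001d045092 reached 8.11 CPM in infected R2 replicate 1.

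Infection calls within each genotype appeared with the replicate block. Differences between the replicate numbers that all groups share are a candidate explanation: the biological coefficient of variation was 0.126 with the real block, and 20 blocks with numbers shuffled within groups gave 0.158 to 0.222. For the averaged blocked count, 1 of 80 splits, the real one, called as many as 1255 genes and the highest other called 319. These splits swapped treatment within pairs separately in each genotype, although same-numbered libraries of both genotypes varied together. Swapping whole replicate numbers would leave too few splits for a share under 0.05. This count therefore argues against a chance assignment of treatment only if the B73 and R2 pairs of a number are separate units. Within a genotype only 8 swaps of pairs exist, too few for a share under 0.05; B73 gave 379 against a highest other of 3, and R2 gave 204 against 0. What made the replicate numbers differ, such as a day or a batch of plants, was not tested, since the labels give neither.

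The blocked infection counts fell furthest when replicate 1 was left out, to 96 in B73 and 32 in R2. Greater sequencing depth of replicate 1 is argued against, because the libraries of replicate 2 total 21471947 counts against 21522320 and their removal left 278 calls in B73, 2.9 times as many as the removal of replicate 1. A larger response in replicate 1 may contribute, since its infection differences had the steepest slope on the mean response of the other numbers in the other genotype, 0.501 in B73 and 0.474 in R2, against at most 0.400 and 0.380 for the other numbers. No biological explanation for such a difference was tested, and the slope was looked at after the counts were seen.

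Without the block, splits of the libraries gave the following. For genotype, 1 of 35 splits, the real one, gave as many genes in mock leaves (227, highest other 0) and 1 of 35 in infected leaves (243, highest other 63). The split with 63 genes set replicates 1 and 2 against 3 and 4, and the 7 other splits that part all 4 pairs called 0. Since the numbers pair the libraries, only those 7 are comparable with the real split. They are too few for a share under 0.05, so these counts alone do not exclude chance. For infection averaged over genotypes, 2 of 80 splits called as many as the real 52, and the highest other, 68, set mostly replicates 3 and 4 against 1 and 2 and parted 2 of 8 pairs; the 5 others drawn that part all 8 pairs called 0. Only those 5 are comparable with the real split in parting all pairs, too few for a share under 0.05. This count without the block therefore does not exclude chance, and the blocked value of 1255 is given above. For infection in B73 and in R2 the real count was 0, so all 35 splits necessarily called as many and this count says nothing about chance. The highest others were 183 in B73 and 7 in R2. The split with 183 set both replicate 2 libraries against both replicate 3 libraries. It also parted replicates 1 and 4 by treatment, so it mixes replicate number with treatment. In both B73 and R2, the split of replicates 1 and 2 against 3 and 4 called 7 genes, which points to a structure of the samples by replicate number. For the interaction the real count was also 0, so all 80 splits necessarily called as many, with a highest of 2, and there is no called gene for chance to explain.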

How the results depend on the processing

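The combinations of the replicate block with another setting were chosen after the data were seen, as were the window results from infected libraries and from blocked calls. Numbers of called genes are given in the order infection in B73, infection in R2, infection averaged over genotypes, genotype in mock and genotype in infected. Without the block they were 0, 0, 52, 227 and 243, with 0 for the interaction. DESeq2 size factors and limma kept every count within 1.5 times of these. The Wald test of DESeq2 gave 21, 18 and 277 for the infection comparisons. Without an expression filter, infection in R2 gave 2 and the average 82. With 1 library of the groups compared left out, the count was 0 in B73, 0 to 1 in R2, 0 for the interaction, 16 to 97 for the average, 177 to 201 for genotype in mock and 186 to 216 in infected leaves.

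With the replicate block the counts were 379, 204, 1255, 540 and 595. They were 382, 205, 1256, 537 and 596 with the block and DESeq2 size factors, 423, 276, 1140, 550 and 576 with the block in DESeq2, and 329, 221, 1254, 548 and 631 with the block in limma. With the block and no expression filter they were 985, 649, 1737, 965 and 1033, and 17 for the interaction. With the block in a fit of only the groups compared, the comparisons of 2 groups gave 499, 330, 616 and 656. With the block and without replicate 1 the counts were 96, 32, 476, 410 and 413; without replicate 2, 278, 128, 898, 420 and 445; without replicate 3, 514, 133, 1130, 433 and 432; without replicate 4, 174, 129, 816, 362 and 455. The block thus moved all 5 of these counts and left the interaction at 0. The fits with a number left out also held fewer libraries, and the effect of that alone was not tested. Without replicate 3 the count in B73 rose from 379 to 514. For the rise with the block, the test of shuffled blocks is given above, with a coefficient of variation of 0.126 for the real block. For the remaining changes the cause was not tested.

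The correlation of the infection responses moved from 0.48 to 0.10 without an expression filter, with or without the block, and to 0.36 with the block and without replicate 1. With 1 library left out it was 0.38 to 0.50. The clustering in the gene order passed its test in all 3 alternatives, with highest window shares of 30% to 40%. Of 472 values of named genes under alternatives, 389 kept their direction and their side of the threshold, 60 passed it newly, all for infection within a genotype, 22 lost their call and 1 changed direction without a call before or after. All 184 values of the named genotype differences stayed called. With limma on log2 of the deposited CPM, the averaged infection fold change was 1.75 for Zm00001d045092 and 1.25 for Zm00001d051080 on the log2 scale, against 2.79 for both. That scale, with a pseudocount added, lowers the fold of genes with few counts, and it gave 3.33 to 3.92 for the named genes higher in R2 and -5.24 to -3.43 for those lower in R2. The 1 change of direction was that of Zm00001d048192 in R2. Its log2 fold change ran from -4.91 without infected R2 replicate 2 to 0.44 without mock R2 replicate 2. Replicate 2 had 44.1 CPM in mock R2 and 11.5 CPM in infected R2. The other libraries had at most 3.87 CPM in mock R2 and 0.753 CPM in infected R2. Leaving out either replicate 2 library therefore moves the mean of its group. The gene lists and the level of pan1 were not run under any setting. Depth limits the fold of genes without counts to lower bounds.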

Other observations

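The tests of the clustered genotype differences were written out after the clustering was seen, although the random placements had been planned before the data were examined. Those of lost reads were also written after the numbers of higher and lower genes were seen.

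Genes called for infection were not more frequent inside the segments in which R2 and B73 differ than outside, though this difference was not tested. With the replicate block, 6.50% of the tested genes inside the segments were called for infection averaged over genotypes, against 7.29% outside. Genes called between genotypes had a median absolute log2 fold change of 1.69 inside the segments and 1.34 outside. Of the 18 genes without any count in B73, 2 lay inside the segments, and of the 11 without any count in R2, 7 did.

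For the clustering of genotype differences, 3 candidate explanations were considered. Chance placement is argued against by the window share of 32.0%, above the 18% reached by random placements. Loss of reads of another haplotype in mapping to B73 would by itself only lower a gene's value. It therefore leaves unexplained the genes higher in R2, 33.0% of the called genes inside the segments (Wilson 95% interval 25.0 to 42.2%). This follows from the direction alone and is not an independent test. For the genes lower in R2 it cannot be told apart from lower expression, because both lower the counts. Their share of 67.0% inside against 58.3% outside (Fisher's exact p 0.217) does not decide between them. A hypothesis that stays open is that a chromosome segment from another parent was carried along with the pan1 mutation: the interpolated place of pan1 may lie in the larger segment, 217 rows from its nearest edge against an error of at most 177 rows in intervals as long as the 2008 rows around pan1. That segment covers 64.9% of the rows between the flanking microRNA genes, the mutation itself as the source of single differences was not tested, and 115 of the 227 called genes lie outside the segments.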
